A study of Mus musculus with 6 samples.

How the data were processed

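Thioglycollate-elicited peritoneal macrophages were taken from 3 Tet2-deficient mice and 3 wild-type littermates (C57BL/6J), on day 4 after an intraperitoneal injection of 1 mL of 4% Brewer's medium, per the labels' protocols. They were cultured with 10% fetal bovine serum and treated for 10 h with 10 ng/mL lipopolysaccharide and 2 ng/mL interferon gamma, and total RNA of each culture was hybridised to 1 Affymetrix whole-transcript array. The labels call the 3 samples of a group biological replicates and the series design gives 3 mice per group, so p-values measure the spread between mice and their cultures. The array type, the probe set definition, the genome build and any filter on features are not given in the sources used here.

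The values are log2 expression as deposited by the authors, made with RMA (background correction, normalization between arrays and summary over probes) with the affy package 1.36.1, per the submitters' processing notes. They run from 0.35 to 12.7 with 1 feature per gene. The sorted values differ between arrays by at most 0.27, so the arrays were used as deposited and not normalized again. RMA draws all arrays to 1 shared distribution, so a change of all genes alike could not be seen in these values, and levels near the floor understate folds. No pair of arrays held the same values: in each pair at least 99.66% of features differed. No depth applies to arrays, and the number of arrays limits the precision. Of 25206 features, 23185 had 1 gene symbol in the platform annotation, 0 had several and 2021 had none; features without a symbol were tested but not named. Every named feature matched a gene of the mouse RefSeq table of assembly GRCm38.p6, which was used for names, neighbours and genomic spans (23182 features with a span) and from which no coordinate is given.

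The comparison, Tet2-deficient minus wild-type, was fitted over all features with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The prior had 5.31 degrees of freedom. A permutation test of 1 gene with 3 arrays against 3 cannot give a two-sided p below 0.1, so none was used. Gene lists (28 pathway lists and 10 lists of cell type markers) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 38 lists. Camera compares a list with all other features; fry asks whether the genes of a list move, on balance, one way. Of 802 listed genes, 743 were measured. Older symbols were matched through synonyms for 3 of them. Within each list, genes were also adjusted over the list alone. The sample groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

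Genes were named by this rule: Tet2, Tet1, Tet3, Hdac2, Nfkbiz, Il6, Il1b, Tnf, Cxcl1, Cxcl2, Cxcl3, Pf4, Nos2 and Arg1 always; the 10 largest rises and 10 largest falls among named genes past the threshold whose groups did not overlap, leaving out predicted genes and small RNAs; and up to 4 members with the smallest p in each list described. Il12b, Il15, Tlr9, Mmp2, Tgfb2, Icosl, Hsd17b7, Vegfa, Gadd45a, Mmp9, Gata6, Rplp0, Rpl3, Rpl5, Rps2, Rps15, the small RNAs and the members of gene families in the closing section were named after their values were seen.

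The alternatives were arrays centred on their medians, cyclic loess between arrays, features above the median level only, a replicate block, eBayes with trend and robust fitting, array weights, each array left out in turn, other thresholds, camera with an estimated correlation, fry, and features with 1 symbol only. Averaging several features of a gene was planned but changes nothing, since each gene had 1 feature. The removal of a gene-span trend was added after the data were examined. It used a loess fit of each array's deviations on log2 span and mean log2 level together (loess span 0.3), so a trend with level was removed too. The fits were tested on simulated data with the real means and spread over 25206 features: 67% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were called, 100% of these in the right direction, and 5.23% of calls were unchanged genes. In the simulation 0 of 20 unchanged lists were called. Its genes varied independently of each other, so it does not test set calls at the preset correlation where genes of a list move together. Estimated correlations reached 0.65, for genes induced by type I interferon, and were below 0 for some lists, such as matrix proteases (-0.018). For that list the unadjusted camera p was 1.11e-06 at the preset and 0.00576 at the estimated correlation. Camera at an estimated correlation also takes its p from the few residual degrees of freedom of the arrays. A call lost under it is thus no measure of how far genes of a list move together.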

Results

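Gene expression was measured in mouse peritoneal macrophages, phagocytes of the abdominal cavity drawn there by an injection of thioglycollate broth, an irritant that recruits monocytes and macrophages. The cells came from 3 mice labelled as lacking Tet2, an enzyme that oxidises 5-methylcytosine in DNA, and from 3 wild-type littermates on the C57BL/6J background. All cultures had received lipopolysaccharide, a bacterial ligand of toll-like receptor 4, together with interferon gamma for 10 h, so no unstimulated culture entered the comparison and every value below describes the stimulated state. Each culture gave 1 whole-transcript array with log2 expression values for 25206 gene-level features. Median log2 values per array lay between 3.54 and 3.66 in the wild-type group and between 3.47 and 3.60 in the group labelled Tet2-deficient. Pearson correlations over all features were 0.989 to 0.991 within the Tet2-deficient group, 0.988 to 0.990 within the wild-type group and 0.983 to 0.988 between the groups. The first principal component held 38% of the variance and separated the groups. Log2 changes are given as Tet2-deficient minus wild-type with the standard error of the limma fit (n = 3 arrays per group), and the number of arrays limits their precision.

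The Tet2 feature was not lower in the arrays labelled Tet2-deficient. Its log2 level was 5.55, 5.25 and 5.75 in those 3 arrays and 5.40, 5.07 and 5.10 in the 3 wild-type arrays. The log2 change was 0.32 ± 0.16, with a limma adjusted p = 0.365. Neither the deleted part of the gene nor the position of the probes is given in the sources used here, so a feature that reads transcript outside the deletion would check nothing, and every direction below rests on the sample labels. The related enzymes Tet1 (log2 change -0.24 ± 0.17, adjusted p = 0.558) and Tet3 (0.17 ± 0.16, adjusted p = 0.676) did not pass the threshold either.

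The comparison asked which genes differ in level, under an inflammatory stimulus, between macrophages labelled Tet2-deficient and wild-type ones. Transcripts that were higher in macrophages labelled Tet2-deficient included those of the cytokine Il6 (2.46-fold, log2 change 1.30 ± 0.24, adjusted p = 0.0477) and the neutrophil-attracting chemokines Cxcl1 (3.30-fold, 1.72 ± 0.28, adjusted p = 0.0290), Cxcl2 (2.65-fold, 1.40 ± 0.21, adjusted p = 0.0220) and Cxcl3 (3.64-fold, 1.87 ± 0.32, adjusted p = 0.0361). They were among 6 of 22 pro-inflammatory cytokine genes and 3 of 15 CXC chemokine genes that rose. The integrin subunit Itgb8 was at 5.11-fold and the matrix protein fibronectin, Fn1, at 3.43-fold the wild-type level, both past the threshold. Itgb8 stayed past it whichever array was left out, whereas Fn1 lost its call in 5 of these 6 fits (adjusted p = 0.011 to 0.101). The interferon-inducible lysosomal thiol reductase Ifi30 fell by 1.79 on the log2 scale and the monocyte-attracting chemokine Ccl8 fell by 2.03. For other widely used readouts of macrophage activation no change passed the threshold: Tnf (log2 change 0.32 ± 0.12, adjusted p = 0.221), Nos2, the inducible nitric oxide synthase (-0.21 ± 0.12, adjusted p = 0.422), Arg1, arginase 1 (0.42 ± 0.25, adjusted p = 0.469), and Il1b, which lay just above it (0.63 ± 0.13, adjusted p = 0.0553). Of these 4, Tnf passed under 1 of 13 alternatives (a trended and robust prior, adjusted p = 0.0437) and Il1b under 6 of 13 (lowest adjusted p = 0.00558). Conversely, Il6 lost its call under 8 of the 13, Cxcl1 and Cxcl2 under 4 each and Cxcl3 under 5, so Il6 was no firmer than Il1b.

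**Figure D1:**
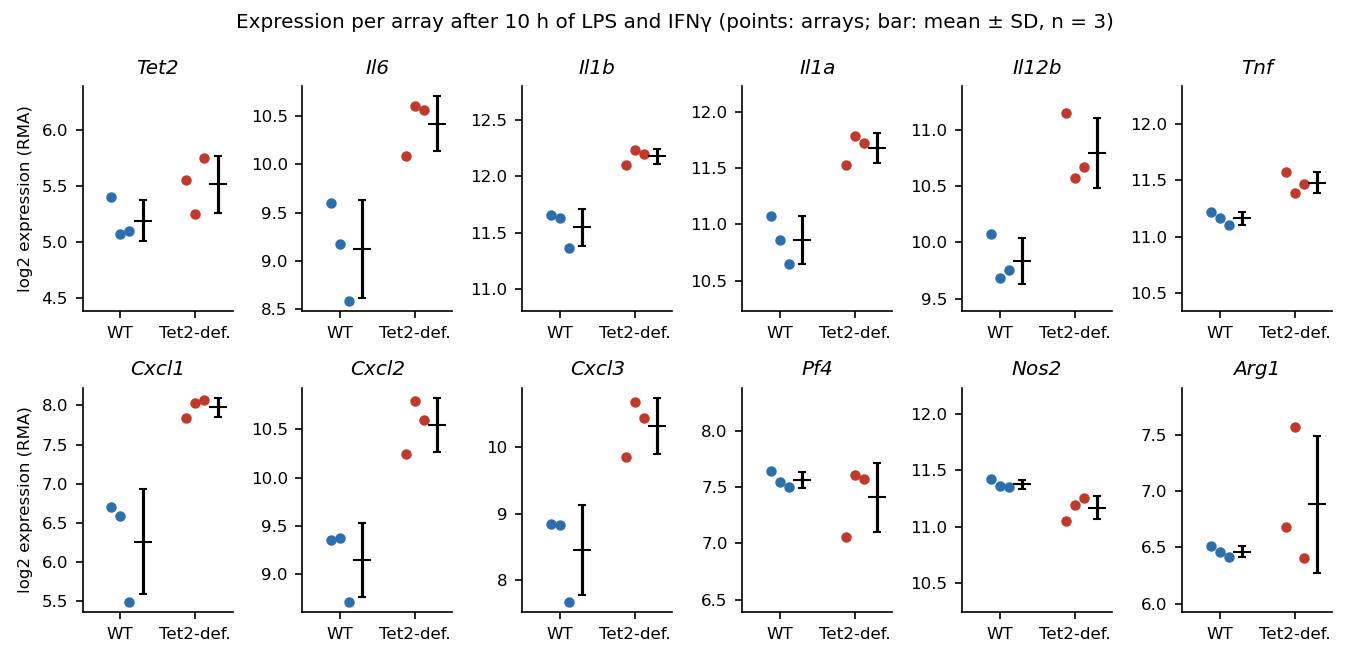
Log2 expression (vertical axis) of 12 genes in each array; blue points are the 3 wild-type arrays, red points the 3 arrays labelled Tet2-deficient, and black bars the mean with its SD. The groups do not overlap for Il6, Il1a, Il12b, Cxcl1, Cxcl2 and Cxcl3, nor for Il1b, Tnf and Nos2, which did not pass the threshold. They overlap for Tet2, Pf4 and Arg1. Over all features 22% had groups that did not overlap.

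In total 240 of 25206 features passed an adjusted p of 0.05, 163 higher and 77 lower in the arrays labelled Tet2-deficient, and 228 of them carried a gene symbol. Their absolute log2 changes ran from 0.58 to 2.83, and 94 changed at least 2-fold (65 higher, 29 lower). All 240 had groups that did not overlap. Over all features 5538 (22%) had such groups, where chance gives 10%. At an adjusted p under 0.25 there were 3026 features (1500 higher, 1526 lower), and 4035 had an unadjusted p under 0.05. The share of higher features among those past the threshold was 67.9% as deposited, 78.8% after each array was centred on its median and 59.6% with cyclic loess between arrays. The count was 846 when dim features were left out, 814 with a trended and robust prior and 498 with array weights. Leaving out wild-type replicate 1, 2 or 3 gave 155, 67 and 25 features, and leaving out Tet2-deficient replicate 1, 2 or 3 gave 27, 114 and 11. Of the 51 genes named by rule that passed the threshold, 7 stayed past it whichever array was left out: Stfa3, Itgb8, Epha4, Scgb1a1, Ifi30, Thbs4 and Plau. The other 44 lost it in at least 1 of these 6 fits, among them 8 that lost it in all 6 (Ifi213, Ifi204, Irak3, Tab2, C5ar1, Clec7a, Ctsl and Sgms2), with 11, 26 and 37 lost without wild-type replicate 1, 2 or 3 and 36, 21 and 44 lost without Tet2-deficient replicate 1, 2 or 3. Such losses are repeated below for some genes only. Ccl3, Timd4, Itgam, Cat and Pdgfrb, for which they are not repeated, lost the threshold in 5 of the 6 fits each. Of the 63 genes named by rule that did not pass, 34 passed under at least 1 of 13 alternatives, most often Ly6c2 (7) and Alox15, Il1b, P2rx7 and Ptgs2 (6 each).

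Among named genes other than predicted genes and small RNAs, the largest measured rise was that of Stfa3, a stefin that inhibits cysteine proteases (log2 change 2.83 ± 0.24, adjusted p = 0.00281). Its wild-type log2 levels of 3.04, 2.98 and 2.59 lay below the array medians, where a change can be understated. Next came Prg4, the lubricating proteoglycan lubricin (5.50-fold, 2.46 ± 0.31, adjusted p = 0.0152), Itgb8 (2.35 ± 0.16, adjusted p = 9.20e-04) and the non-coding transcript AI504432 (2.03 ± 0.29, adjusted p = 0.0210). The others of the 10 largest rises, with log2 changes of 1.76 to 1.87, were Cxcl3, coagulation factor V (F5), tissue factor (F3), Fn1, the cystine transporter subunit Slc7a11 and the ephrin receptor Epha4. The largest measured fall was that of Scgb1a1, a secretoglobin best known from airway club cells (-2.47 ± 0.16, adjusted p = 9.20e-04), which in the Tet2-deficient arrays lay below the array medians at a mean log2 level of 3.15. It was followed by Ccl8 (-2.03 ± 0.26, adjusted p = 0.0152), Hamp, which encodes the iron-regulating peptide hepcidin (-1.86 ± 0.21, adjusted p = 0.00832), Ifi30 (-1.79 ± 0.12, adjusted p = 9.20e-04) and the antiproliferative gene Btg3 (-1.76 ± 0.21, adjusted p = 0.0119). The thrombospondin Thbs4 (-1.62), the urokinase gene Plau (-1.52), the schlafen Slfn4 (-1.32), the DNA sensor family member Ifi213 (-1.24) and the mitochondrial aldehyde dehydrogenase Aldh1b1 (-1.22) completed the 10 largest falls. Among these 20 genes, Ifi213 alone lost the threshold whichever array was left out (adjusted p = 0.0647 to 0.157). Cxcl3, F3, Fn1 and Slfn4 lost it in 5 of the 6 fits. Only Stfa3, Itgb8, Epha4, Scgb1a1, Ifi30, Thbs4 and Plau kept it in all 6.

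**Figure D2:**
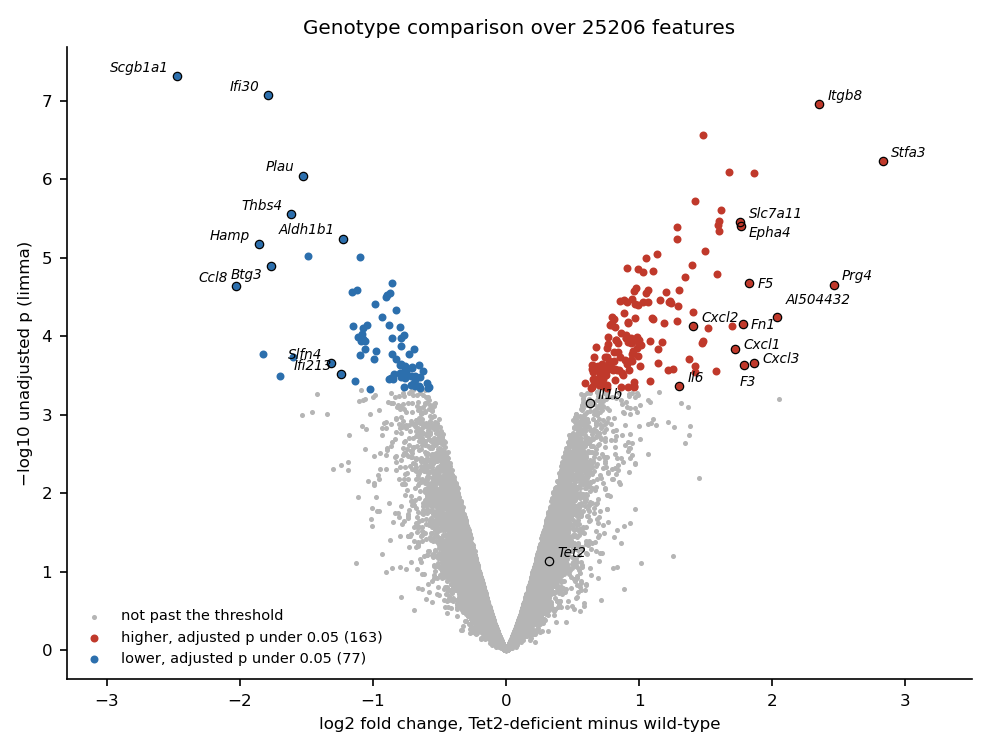
Log2 fold change between the groups (horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for 25206 features; red and blue points are the 163 higher and 77 lower features past an adjusted p of 0.05. Scgb1a1 and Ifi30 have the smallest p among the falls, Itgb8 and Stfa3 lie among the strongest rises, and Tet2 lies below the threshold.

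Pro-inflammatory cytokine genes had a median log2 change of 0.59, the highest median of the 38 lists. Of 22 measured, 6 rose, 0 fell and 16 did not pass. The 6 were Inhba, a subunit of activin A (1.59 ± 0.17, adjusted p = 0.00629), oncostatin M, Osm (1.23 ± 0.17, adjusted p = 0.0162), the macrophage growth factor Csf1 (1.11 ± 0.13, adjusted p = 0.0121), Il1a (0.82 ± 0.14, adjusted p = 0.0376), Il6, and Il12b, a subunit of interleukin 12 (0.96, adjusted p = 0.0447). Adjusted over the list alone, 15 rose and 1 fell, the fall being that of Il15 (log2 change -0.74). The list rose as a set with camera (adjusted p = 4.39e-11), with an adjusted p = 0.13 with an estimated correlation. Markers of resident peritoneal macrophages rose as a set in the same arrays (median log2 change 0.23, camera adjusted p = 3.42e-07), with an adjusted p = 0.298 with an estimated correlation and 0.0601 with fry, and this rise stood beside the changes of every other list below. Il6 lost its call without any 1 of 5 arrays, all but wild-type replicate 1 (adjusted p over the 6 fits 0.0287 to 0.175), and with cyclic loess between arrays (0.0567). Il1a lost its call without the same 5 arrays (0.0399 to 0.154).

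Of 15 CXC chemokine genes 3 rose (Cxcl1, Cxcl2 and Cxcl3), 0 fell and 12 did not pass. The neutrophil chemoattractant Cxcl5 had a log2 change of 1.10 ± 0.24 (adjusted p = 0.0673), and Pf4, platelet factor 4, had -0.15 ± 0.16 (adjusted p = 0.701). When adjusted over the list alone, 5 rose and 0 fell. The list rose as a set (camera adjusted p = 0.00325), with an adjusted p = 0.298 with an estimated correlation. CC chemokine genes moved both ways: among 16, Ccl3 rose (0.97 ± 0.13, adjusted p = 0.0162), Ccl8 fell and 14 did not pass, and 4 rose and 1 fell adjusted over the list alone. As a set the CC chemokines did not pass (camera adjusted p = 0.234). Ccl4 (0.63 ± 0.13, adjusted p = 0.0553) and Ccl22 (0.74 ± 0.18, adjusted p = 0.0926) were short of the threshold. Leaving out any 1 Tet2-deficient array ended the calls of Cxcl1, Cxcl2 and Cxcl3, and leaving out wild-type replicate 2 ended those of Cxcl1 and Cxcl3 and wild-type replicate 3 those of Cxcl2 and Cxcl3 (adjusted p over the 6 fits 0.0161 to 0.127, 0.0346 to 0.108 and 0.0449 to 0.145).

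Of 26 components of toll-like receptor signalling 5 rose, 0 fell and 21 did not pass. As a set these genes rose with camera (adjusted p = 1.05e-05), with an adjusted p = 0.424 with an estimated correlation. The 5 were the lipopolysaccharide co-receptor Cd14 (0.97 ± 0.13, adjusted p = 0.0152), the lipoprotein receptor Tlr2 (0.96 ± 0.13, adjusted p = 0.0152), the lipopolysaccharide-binding protein Lbp (0.94 ± 0.15, adjusted p = 0.0266), the adaptor Tab2 (0.75 ± 0.13, adjusted p = 0.0377) and Irak3, an inhibitory kinase-like protein of the pathway (0.71 ± 0.13, adjusted p = 0.0423). Adjusted over the list alone, 10 rose and 1 fell, the fall being that of Tlr9 (log2 change -1.06). NF-kB pathway and feedback genes rose as a set (camera adjusted p = 1.66e-05), with an adjusted p = 0.298 with an estimated correlation. Among 23 of them, Traf1 (0.87 ± 0.16, adjusted p = 0.0389) and Irak3 rose, 0 fell and 21 did not pass, whereas 6 rose and 0 fell adjusted over the list alone. The feedback inhibitor Tnfaip3 (0.50 ± 0.12, adjusted p = 0.0843), the stress-response gene Ier3 (0.56 ± 0.15, adjusted p = 0.120) and the nuclear cofactor Nfkbiz (0.48 ± 0.14, adjusted p = 0.129) were not past the threshold. Markers of resident peritoneal macrophages (camera adjusted p = 3.42e-07) and of monocytes (0.00701) rose as sets in the same arrays, with an adjusted p = 0.298 and 0.454 with an estimated correlation, and Cd14 also stood on the list of general macrophage markers. Tab2 and Irak3 lost their calls without any 1 of the 6 arrays (adjusted p = 0.0571 to 0.151 and 0.0628 to 0.157). Traf1 and Lbp lost theirs without any 1 of 5 arrays, all but Tet2-deficient replicate 2 (0.0401 to 0.155 and 0.0333 to 0.115).

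Of 22 anti-inflammatory mediators 0 rose and 0 fell at the gene level, and 1 rose, Ptgs2, adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, had a log2 change of 0.75 ± 0.15 (adjusted p = 0.0522) and Ptges, a prostaglandin synthase, 0.64 ± 0.18 (adjusted p = 0.123). These prostaglandin enzymes had the smallest p in the list, so a rise of the list is no measure of anti-inflammatory activity. The list rose as a set (camera adjusted p = 0.0354), with an adjusted p = 0.424 with an estimated correlation. That call ended without wild-type replicate 3 or without Tet2-deficient replicate 1 or 3, the adjusted p over the 6 fits being 0.0169 to 0.136. Inflammasome genes did not pass as a set (camera adjusted p = 0.652), with 0 of 22 past the threshold. Adjusted over the list alone, 3 of them rose and 2 fell. The sensor Nlrp3 had a log2 change of 0.68 ± 0.15 (adjusted p = 0.0749) and the ATP-gated channel P2rx7 -0.80 ± 0.16 (adjusted p = 0.0527).

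Of 29 genes induced by type I interferon 0 rose, 1 fell and 28 did not pass, and 22 of the 29 had a negative change with a median of -0.22. The list fell as a set (camera adjusted p = 0.00325), with an adjusted p = 0.620 with an estimated correlation. The fall was that of Ifi204, a sensor of cytosolic DNA (-0.72 ± 0.12, adjusted p = 0.0315), and Mx1, a transcribed pseudogene in the RefSeq table, had -0.83 ± 0.20 (adjusted p = 0.0827). Adjusted over the list alone, 0 rose and 2 fell. The set call ended without wild-type replicate 3 or Tet2-deficient replicate 2, the adjusted p over the 6 fits being 1.36e-04 to 0.223, and Ifi204 lost its call without any 1 of the 6 arrays (0.0718 to 0.134) and after centring on array medians (0.0552). Targets of interferon gamma did not pass as a set (camera adjusted p = 0.475), with 0 of 24 past the threshold and 2 rising and 1 falling adjusted over the list alone. Among them the guanylate-binding protein Gbp4 had a log2 change of 0.90 ± 0.18 (adjusted p = 0.0553) and the transcription factor Irf8 -0.45 ± 0.13 (adjusted p = 0.124). Of 14 genes of MHC class II presentation 0 rose and 1 fell, Ifi30, and 3 rose and 2 fell adjusted over the list alone. That list did not pass (camera adjusted p = 0.332). Its master regulator Ciita had a log2 change of 0.89 ± 0.19 (adjusted p = 0.0615), and the class II chain H2-Aa had 0.59 ± 0.15 (adjusted p = 0.103).

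Matrix proteases and remodelling genes changed in both directions, with 5 of 23 higher, 1 lower and 17 not past the threshold. Fn1 rose by 1.78 ± 0.26 (adjusted p = 0.0219), Serpinb2, an inhibitor of plasminogen activators, by 1.59 ± 0.20 (adjusted p = 0.0128), thrombospondin 1, Thbs1, by 1.40 ± 0.17 (adjusted p = 0.0119), the collagenase Mmp13 by 1.03 ± 0.14 (adjusted p = 0.0162), and the gelatinase Mmp2 by 0.81 (adjusted p = 0.0377). Plau, the plasminogen activator urokinase, fell by 1.52 ± 0.13 (adjusted p = 0.00281). When adjusted over the list alone, 9 rose and 2 fell. The list rose as a set (camera adjusted p = 1.05e-05), with an adjusted p = 0.13 with an estimated correlation. Markers of mesothelium and fibroblasts rose as a set too (camera adjusted p = 0.0360), with an adjusted p = 0.596 with an estimated correlation, but not array by array. Their mean deviations were 0.078, 0.570 and -0.175 in Tet2-deficient replicates 1, 2 and 3 and -0.313, 0.0739 and -0.234 in wild-type replicates 1, 2 and 3. For the matrix list they were 0.188, 0.264 and 0.164, and -0.149, -0.2035 and -0.2635. Complement and coagulation genes did not pass as a set (camera adjusted p = 0.0508), but passed with arrays centred on their medians (0.0456), with array weights (0.0477), without wild-type replicate 1 (0.0231) and without Tet2-deficient replicate 2 (0.0197). Of 22, 3 rose, 0 fell and 19 did not pass, and 6 rose and 1 fell adjusted over the list alone. F5 (1.83 ± 0.23, adjusted p = 0.0152), F3, which starts the extrinsic clotting cascade (1.79 ± 0.31, adjusted p = 0.0361), and the anaphylatoxin receptor C5ar1 (0.69 ± 0.12, adjusted p = 0.0377) were the 3 that rose. F3 and Fn1 lost their calls without any 1 of 5 arrays, all but wild-type replicate 1 (adjusted p over the 6 fits 0.0135 to 0.149 and 0.011 to 0.101). F5 lost its call without replicate 3 of either group (0.00625 to 0.074). F5 and Thbs1 also stood on the list of resident peritoneal macrophage markers, which passed as a set at the preset correlation but had an adjusted p = 0.298 with an estimated correlation.

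**Figure D3:**
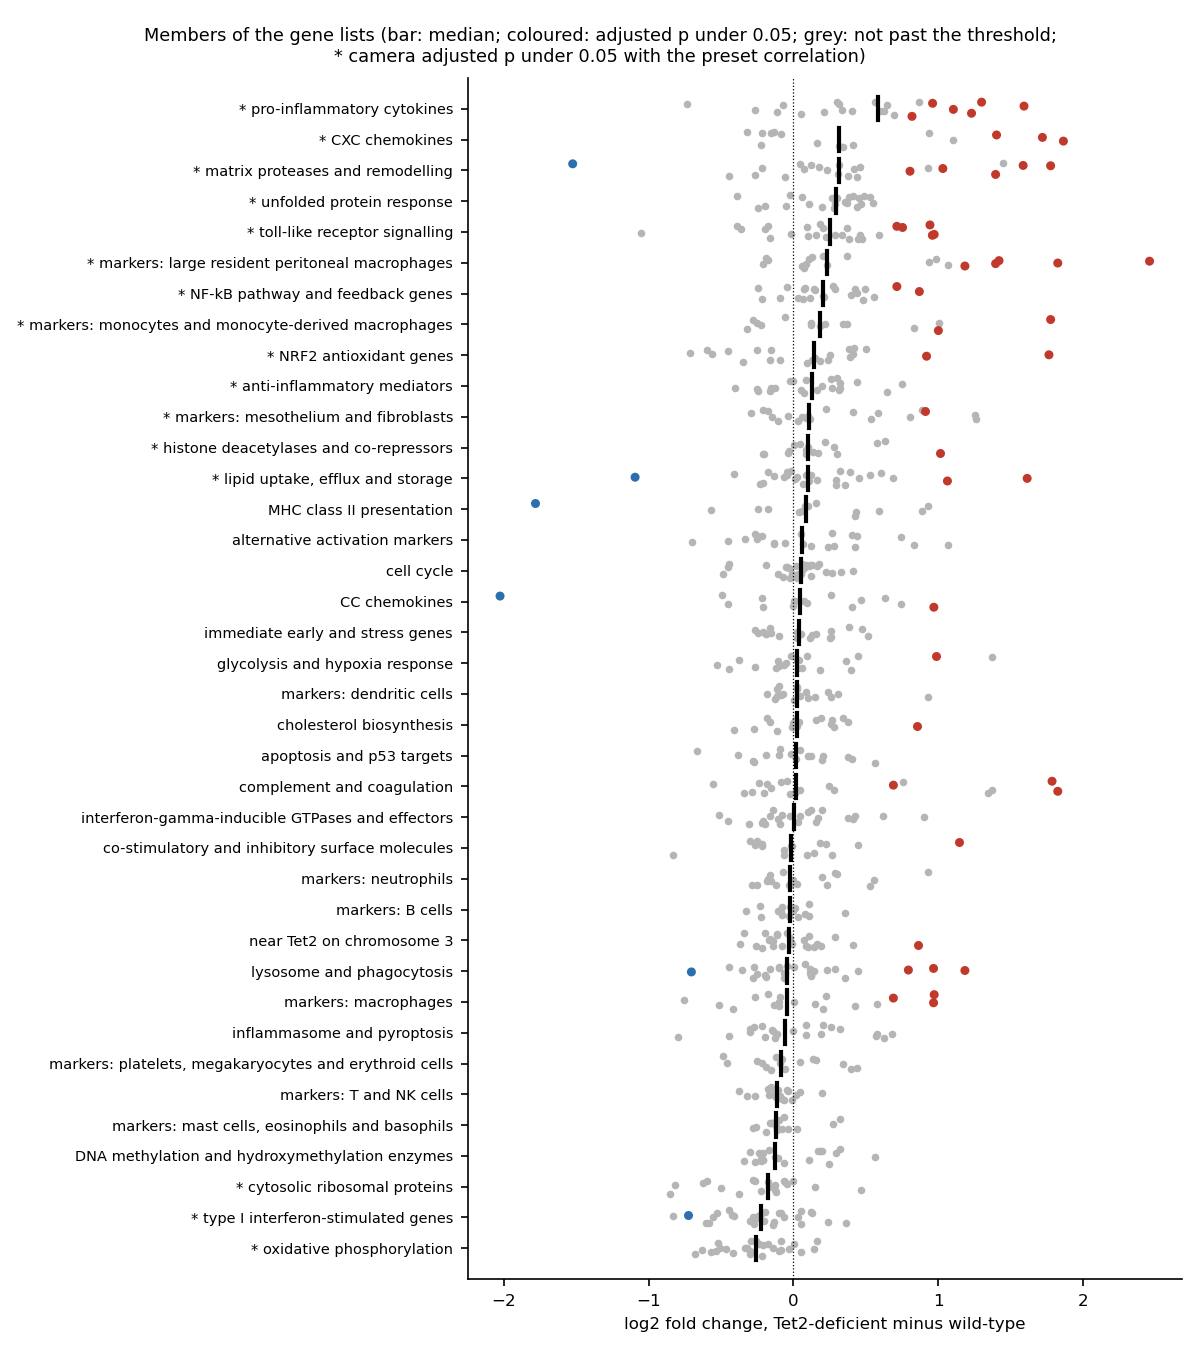
Log2 fold change (horizontal axis) of each measured member of the 38 gene lists, ordered by the list median (black bar); red and blue points are members past an adjusted p of 0.05, grey points did not pass, and asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation. The cytokine list has the highest median, 0.59, and the oxidative phosphorylation list the lowest, -0.26.

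Of 28 genes of lipid handling 2 rose, 1 fell and 25 did not pass, and 7 rose and 1 fell adjusted over the list alone. The oxidised-lipoprotein receptor Olr1 rose (3.06-fold, 1.62 ± 0.16, adjusted p = 0.00624), as did the cholesterol exporter Abca1 (2.09-fold, 1.06 ± 0.15, adjusted p = 0.0162), whereas the fatty acid-binding protein Fabp4 fell by 1.09 ± 0.13 (adjusted p = 0.0102). The list rose as a set (camera adjusted p = 0.00497), with an adjusted p = 0.424 with an estimated correlation. That set call ended without Tet2-deficient replicate 1 (adjusted p over the 6 fits 0.00175 to 0.0598), with cyclic loess (0.0588), with features above the median level (0.125) and with fry (0.0969). Of 22 antioxidant genes of the NRF2 pathway, Slc7a11 (3.40-fold, 1.77 ± 0.18, adjusted p = 0.00629) and catalase, Cat (0.92 ± 0.14, adjusted p = 0.0219), rose, 0 fell and 20 did not pass. Adjusted over the list alone, 7 rose and 3 fell. Camera gave an adjusted p = 0.0477 for this list, with an adjusted p = 0.298 with an estimated correlation, and 5 of the 6 fits that left out 1 array ended the call, all but that without Tet2-deficient replicate 3 (adjusted p = 0.0418 to 0.106).

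Of 27 nuclear genes of oxidative phosphorylation 0 rose, 0 fell and 27 did not pass, and 23 had a negative change with a median of -0.26. The list fell as a set (camera adjusted p = 5.80e-05), with an adjusted p = 0.298 with an estimated correlation. Adjusted over the list alone, 0 rose and 5 fell, among them Uqcrq (-0.68 ± 0.15, adjusted p = 0.0715) and Cox4i1 (-0.63 ± 0.15, adjusted p = 0.0820). Cytosolic ribosomal protein genes also fell as a set (camera adjusted p = 0.0389), with an adjusted p = 0.588 with an estimated correlation. Of 20 measured, 0 rose and 0 fell, and 1 fell, Rps20 (-0.82 ± 0.17, adjusted p = 0.0570), adjusted over the list alone. The ribosomal call ended without wild-type replicate 2 or 3 and without Tet2-deficient replicate 1 or 3 (adjusted p over the 6 fits 0.00247 to 0.186), with features above the median level (0.0772) and with the gene-span trend removed (0.166). Ribosomal protein transcripts are abundant in most cells, yet 5 of the 20 features (Rplp0, Rpl3, Rpl5, Rps2 and Rps15) had wild-type mean log2 levels of 2.69 to 3.49, below the median of every wild-type array, and such features may not measure their transcripts. Genes of the unfolded protein response rose as a set (median 0.29, camera adjusted p = 1.82e-05), with an adjusted p = 0.298 with an estimated correlation. Of its 22 genes 0 rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone. The stress kinase Eif2ak3 had a log2 change of 0.49 ± 0.11 (adjusted p = 0.0783) and the chaperone Dnajb9 0.55 ± 0.15 (adjusted p = 0.113).

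Histone deacetylases and co-repressors rose as a set (camera adjusted p = 0.00497), with an adjusted p = 0.424 with an estimated correlation. Of 17, Hdac9 rose (1.01 ± 0.16, adjusted p = 0.0274), 0 fell and 16 did not pass, and 2 rose and 0 fell adjusted over the list alone. Hdac2 had a log2 change of 0.05 ± 0.12 (adjusted p = 0.897), Hdac1 0.63 ± 0.21 (adjusted p = 0.179) and Hdac4 0.58 ± 0.15 (adjusted p = 0.106). The set call ended without Tet2-deficient replicate 1 (adjusted p over the 6 fits 0.00175 to 0.107). Hdac9 lost its call without any 1 of 5 arrays, all but wild-type replicate 1 (0.0135 to 0.126). Enzymes of DNA methylation and hydroxymethylation did not pass as a set (camera adjusted p = 0.799), with 0 of 21 past the threshold and 1 rising, Gadd45a (log2 change 0.56), and 0 falling adjusted over the list alone. Genes beside Tet2 on chromosome 3 did not pass as a list either (camera adjusted p = 0.799). Of 26 measured, Sgms2, a sphingomyelin synthase, rose (0.86 ± 0.14, adjusted p = 0.0330), 0 fell and 25 did not pass, with 1 rise and 0 falls adjusted over the list alone. Over all 114 measured genes within 10 Mb of Tet2, Sgms2 was again the 1 called gene (0.877% against 0.952% of all features). The median log2 change of those 114 genes was -0.05, and they did not pass with camera. Sgms2 lost its call without any 1 of the 6 arrays (adjusted p = 0.0527 to 0.138).

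Of 19 markers of large resident peritoneal macrophages, the population present before elicitation, 5 rose, 0 fell and 14 did not pass, and 8 rose and 0 fell adjusted over the list alone. The list rose as a set (camera adjusted p = 3.42e-07), with an adjusted p = 0.298 with an estimated correlation and 0.0601 with fry. The 5 were Prg4, F5, Thbs1, the phosphatidylserine receptor Timd4 (1.19 ± 0.17, adjusted p = 0.0219) and the growth factor Tgfb2 (1.42, adjusted p = 0.0382). The transcription factor Gata6, also on the list, had a log2 change of 0.23 (adjusted p = 0.657). Markers of monocytes and monocyte-derived macrophages rose as a set too (camera adjusted p = 0.00701), with an adjusted p = 0.454 with an estimated correlation. Of 15, Fn1 and the integrin subunit Itga4 (1.00 ± 0.16, adjusted p = 0.0266) rose, 0 fell and 13 did not pass, and 4 rose and 0 fell adjusted over the list alone. The monocyte antigen gene Ly6c2 had a log2 change of 1.01 ± 0.20 (adjusted p = 0.0558). This set call ended without Tet2-deficient replicate 1 (adjusted p over the 6 fits 0.00127 to 0.186). Mesothelium and fibroblast markers rose as a set (camera adjusted p = 0.0360), with an adjusted p = 0.596 with an estimated correlation. Of 20, Pdgfrb rose (0.91 ± 0.16, adjusted p = 0.0361), 0 fell and 19 did not pass, and 2 rose and 0 fell adjusted over the list alone. The fibroblast proteoglycan Dcn had a log2 change of 1.26 ± 0.28 (adjusted p = 0.0715). The mesothelium and fibroblast call ended without wild-type replicate 1 or 3 or Tet2-deficient replicate 2 (adjusted p over the 6 fits 5.67e-04 to 0.303).

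General macrophage markers did not pass as a set (camera adjusted p = 0.208). Of 18, Cd14, C5ar1 and Itgam, the complement receptor subunit (0.97 ± 0.14, adjusted p = 0.0211), rose, 0 fell and 15 did not pass, and 4 rose and 2 fell adjusted over the list alone. The receptor gene Csf1r had a log2 change of 0.58 ± 0.11 (adjusted p = 0.0543). Genes of lysosomes and phagocytosis did not pass as a set (camera adjusted p = 0.365). Of 29, Timd4, Itgam and the fungal glucan receptor Clec7a (0.79 ± 0.12, adjusted p = 0.0219) rose, cathepsin L, Ctsl, fell by 0.70 ± 0.12 (adjusted p = 0.0376) and 25 did not pass, and 3 rose and 1 fell adjusted over the list alone. After each array was centred on its median, Ctsl was not past the threshold (adjusted p = 0.0706). Ctsl (0.0735 to 0.157), Clec7a (0.0527 to 0.0884) and C5ar1 (0.0549 to 0.157) lost their calls without any 1 of the 6 arrays. Alternative activation markers did not pass (camera adjusted p = 0.293), with 0 of 22 past the threshold and 3 rising and 1 falling adjusted over the list alone. Among them Alox15 had a log2 change of 1.07 ± 0.21 (adjusted p = 0.0551), and the mannose receptor Mrc1 had -0.70 ± 0.15 (adjusted p = 0.0701).

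Further lists did not pass as sets, though 3 of them held 1 called gene each. Hsd17b7 (log2 change 0.85, adjusted p = 0.0377) rose among cholesterol biosynthesis genes (camera adjusted p = 0.152), the angiogenic factor Vegfa (0.99, adjusted p = 0.0330) among glycolysis and hypoxia genes (camera adjusted p = 0.365), and Icosl (1.14, adjusted p = 0.0290) among co-stimulatory and inhibitory molecules (camera adjusted p = 0.842). No member was called among markers of neutrophils (camera adjusted p = 0.365), dendritic cells (0.365), T and NK cells (0.208), mast cells, eosinophils and basophils (0.396), platelets and erythroid cells (0.799) or B cells (0.898). With features above the median level the neutrophil list passed (shift against other features 0.494, adjusted p = 0.0247, against 0.11 over all features). No member was called either among immediate early and stress genes (camera adjusted p = 0.275), cell cycle genes (0.412) and apoptosis and p53 targets (0.573). Counts adjusted over the list alone were 1 rise among cholesterol genes, 2 rises and 1 fall among glycolysis genes, 1 rise and 1 fall among co-stimulatory molecules, and 1 rise each among neutrophil markers (Mmp9) and apoptosis genes (Gadd45a), with 0 in the others. In all, 16 of 38 lists passed with camera at the preset correlation (13 up, 3 down), 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 5 with fry, which were cytokines, matrix proteases, NF-kB, oxidative phosphorylation and NRF2 genes. The setting with an estimated correlation also uses fewer degrees of freedom, so its count of 0 cannot be laid to correlation alone. Testing features above the median level ended the set calls of anti-inflammatory (adjusted p = 0.142), lipid handling (0.125), NRF2 (0.165), histone deacetylase (0.0865), ribosomal protein (0.0772) and monocyte marker genes (0.0898). Cyclic loess ended those of anti-inflammatory (0.261), lipid handling (0.0588) and NRF2 genes (0.240). Array weights ended those of mesothelium and fibroblast markers (0.124) and NRF2 genes (0.0726), and centring on array medians that of NRF2 genes (0.0890). Without Tet2-deficient replicate 1 the number with camera was 10. The median of a list was negative while its mean and camera direction were positive for macrophage markers, lysosome, neutrophil, inflammasome and co-stimulatory genes and the genes beside Tet2. For 10 lists, none of them past the camera threshold, the sign of the median differed between the values as deposited and another scaling.

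Array values also varied with gene size and RNA class along the group labels. Over 6525 protein-coding genes with a mean log2 level above 5, the log2 change correlated with the genomic span of the gene (Spearman's rho 0.355 across genes, which are not independent replicates). The median log2 change was -0.12 in the 653 genes with the shortest span, below 4.99 kb, and 0.25 in the 653 with the longest, above 103 kb. Each array's deviation from the gene means correlated with span at -0.138, -0.406 and -0.266 in wild-type replicates 1, 2 and 3 and at 0.251, 0.0856 and 0.435 in Tet2-deficient replicates 1, 2 and 3. A step added after the data were examined removed each array's trend on span and mean level together, so the shares of span and level cannot be told apart. After this removal 233 features passed (134 higher, 99 lower), of which 178 were among the 244 that passed without the removal over the same 23182 features. Removal ended the set calls of lipid handling (camera adjusted p = 0.217), histone deacetylase (0.150), ribosomal protein (0.166) and monocyte marker genes (0.0631), and NRF2 genes, already at 0.0530 over these features, were at 0.191. It also ended the calls of Il6 (1.32 ± 0.25, adjusted p = 0.0521), Irak3 (0.56 ± 0.12, adjusted p = 0.0853) and Sgms2 (0.62 ± 0.14, adjusted p = 0.0934). Of 106 small nucleolar RNAs, which guide RNA modification, 101 had a negative change, with a median of -0.59, and 7 fell, among them Snora36b (-1.82, adjusted p = 0.0315) and Snora81 (-1.70, adjusted p = 0.0409).

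**Figure D4:**
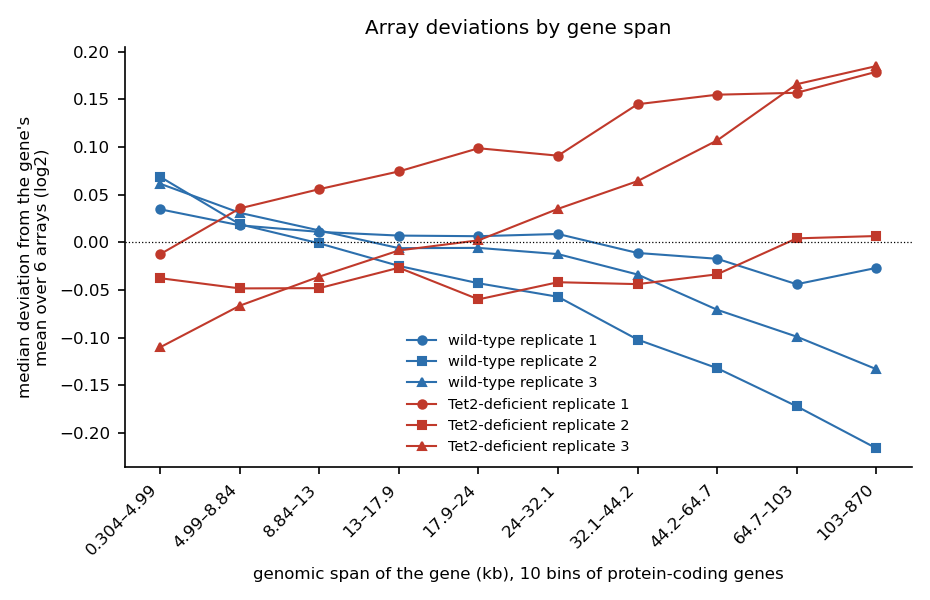
Median deviation of each array from the mean of the 6 arrays (vertical axis, log2) in 10 bins of the protein-coding genes ordered by genomic span (horizontal axis, kb); blue lines are wild-type and red lines Tet2-deficient arrays. In the bin with the longest spans the 3 wild-type arrays lie at -0.0268, -0.216 and -0.133, and the 3 Tet2-deficient arrays at 0.179, 0.00667 and 0.185.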

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

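Tests of the removal of the gene-span trend were chosen after the results were seen; the other alternatives were planned. Tet2 was never past the threshold and its log2 change stayed positive, from 0.186 with the span trend removed to 0.458 without Tet2-deficient replicate 2. Of 16 lists past the camera threshold, 8 stayed past it whichever array was left out (cytokines, CXC chemokines, NF-kB, toll-like receptors, oxidative phosphorylation, matrix proteases, unfolded protein response and resident macrophage markers), and 0 did with an estimated correlation. None of the named genes or lists past the threshold changed direction. The values hold no background level, so signal over background was judged only by leaving out dim features.

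The count of 240 features (163 higher, 77 lower) became 846 (527, 319) with features above the median level, where fewer features are tested, 814 (497, 317) with trend and robust, 498 (318, 180) with array weights, 3026 (1500, 1526) at an adjusted p under 0.25 and 876 (483, 393) at an unadjusted p under 0.05 with 1.5-fold; cyclic loess gave 118 lower features. Leaving out 1 array gave 11 to 155 features (7 to 124 higher, 4 to 46 lower) and 10 to 15 lists, where fewer samples are fitted. The estimated correlation gave 0 lists and fry 5. With the replicate block, 230 features passed, 167 of them among the 240, and the block ended the set call of NRF2 genes (adjusted p = 0.0811) and the calls of 9 named genes, Il6 (0.0695), F3, Il1a, Traf1, Irak3, Hdac9, C5ar1, Ctsl and Sgms2 (0.0506 to 0.0695). Same-numbered arrays deviated together at correlations of 0.0838, 0.191 and 0.0248, all positive, and 4 of 6 arrays correlated best with their own number. Array medians were highest in replicate 2 and lowest in replicate 1 of both groups. A pairing by number is thus not excluded. The main fit had no block because no protocol states that the numbers pair the mice.

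Signs turned only for lists and genes near 0, none past the threshold; a list's value here is its mean log2 change minus that of all other features, and the cause was not tested. With cyclic loess the values were -0.0104 for inflammasome genes, -0.0205 for apoptosis genes, 0.0154 for B cell and 0.00528 for platelet markers and -0.00984 for Hdac2. Above the median level they were -0.0246 for CC chemokines, -0.0542 for co-stimulatory genes, -0.000741 for inflammasome genes, -0.0112 for apoptosis genes and 0.0322 for B cell markers. With the span trend removed they were -0.0176 for co-stimulatory, -0.0213 for inflammasome, -0.00044 for lysosome and -0.0125 for apoptosis genes, -0.0316 for genes beside Tet2, 0.0242 for B cell and 0.0217 for platelet markers, -0.0344 for Tet3, -0.03 for Hdac2 and 0.0277 for Pf4. Leaving out 1 array gave -0.0231 to 0.139 for inflammasome genes, -0.0365 to 0.0245 for DNA methylation enzymes, -0.00271 to 0.0694 for apoptosis genes, -0.143 to 0.128 for B cell markers, -0.0323 to 0.000482 for platelet markers, -0.0292 to 0.0946 for Hdac2 and -0.252 to 0.0228 for Pf4.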

Other observations

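Further called genes are given by gene family; the families were chosen because they held called genes, so their counts are no test of the family. Among 26 integrin subunits 5 rose and 0 fell: Itgb8, Itga1 (log2 change 1.30 ± 0.17, adjusted p = 0.0152), Itga4, Itgam and Itgav (0.79 ± 0.12, adjusted p = 0.0219). Among 32 C-type lectin genes, Clec4n (1.60 ± 0.16, adjusted p = 0.00629), Clec7a and Clec5a (0.77 ± 0.13, adjusted p = 0.0348) rose and Clec4a3 fell by 1.11 ± 0.17 (adjusted p = 0.0264). Of 12 genes of the Ifi200 family of DNA sensors, Ifi213 and Ifi204 fell, 0 rose and 1 had a positive change, with a median log2 change of -0.63. The medians of the integrin and Ifi200 families kept their sign with arrays centred on their medians and with cyclic loess, but Ifi204 was not past the threshold after centring. Of the 228 called genes with a symbol, 182 stood in none of the 38 lists.

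Of 20 small RNA features filed under other classes (small nuclear, Cajal body, RNase P, RNase MRP, telomerase, ribosomal and Y RNAs), 3 fell and 0 rose, and among 529 microRNA features 1 fell, Mir151 (log2 change -0.84, adjusted p = 0.0392). The 3 are classed as RNase P RNA in the RefSeq table: Rprl1 (log2 change -1.12, adjusted p = 0.0152), Rprl2 (-0.99, adjusted p = 0.0343) and Rpph1 (-0.85, adjusted p = 0.0425). Whether their features read separate transcripts was not tested. The Y RNA Rny1 had a log2 change of -0.77 (adjusted p = 0.0531) and Rn7sk, a regulator of transcription elongation, -0.40 (adjusted p = 0.180).

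The tests in the paragraphs below were chosen after the patterns were seen, except that of the splits. The 6 arrays can be split into 3 and 3 in 10 ways. The labelled split gave 240 features, the highest of the other splits gave 0, and 1 of 10 splits gave as many as the labelled one; 10 splits are too few for a share under 0.05.

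Cytokine genes and markers of resident peritoneal macrophages rose as sets in the same arrays at the preset correlation, with an adjusted p = 0.13 and 0.298 with an estimated correlation. A trend of expression with gene span between arrays was argued against as the whole cause for the cytokines, whose median span is 7.5 kb. The trend fitted on span and mean level together gives their 22 members a median log2 change of -0.0306 (-0.108 to 0.18), against a measured median of 0.586. A larger share of resident macrophages in the cultures may account for part of the rise. Such a share would lower the markers of monocyte-derived cells, whose median log2 change was 0.1814. Their set call was made only at the preset correlation. Even there it ended with the span trend removed (camera adjusted p = 0.0631), with features above the median level (0.0898) and without Tet2-deficient replicate 1 (0.186), so these markers do not decide the question. A shift in cell makeup and a higher response per cell cannot be told apart here, because each array read the RNA of a whole stimulated culture and no cell counts were used. Moreover, 8 of the 19 resident markers stand in another list of the 38, and Prg4 and Thbs1 were already at log2 levels of 7.33 and 9.84 in the wild-type arrays. The labelled genotype stays among the open explanations as a hypothesis.

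Small nucleolar RNAs were lower in the arrays labelled Tet2-deficient, with array medians of 0.486, 0.217 and 0.202 around the gene means in wild-type replicates 1, 2 and 3 and of -0.538, 0.00269 and -0.334 in Tet2-deficient replicates 1, 2 and 3. A lower transcript level of the genes that hold them was argued against. The median log2 change of 61 host genes was -0.058 (bootstrap interval over genes, not mice, -0.124 to 0.028), against -0.593 for the 85 nucleolar RNAs inside them. The arrays do not measure the rate at which the host genes are transcribed, so lower transcription of them is not excluded. A lower share of small RNAs of several classes in the extracted or labelled RNA is a candidate explanation. Of the small RNAs filed under other classes, 14 of 14 with a mean log2 level above 5 were lower, with a median of -0.62 (exact two-sided sign test over genes, which are not independent, p = 1.22e-04). They include Rnu3a (-1.18), the U3 nucleolar RNA filed as small nuclear, and Cajal body guide RNAs, so not all stand apart from nucleolar RNAs. Whether such a share came from the handling of the RNA or from the genotype was not tested, since both follow the labels.

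Genes of oxidative phosphorylation, with a median span of 9.1 kb, fell as a set at the preset correlation, in arrays that also differed by gene span. The trend with span was argued against as the whole cause. With the trend on span and mean level removed, the median log2 change was -0.188, against -0.261 before. The set test at the preset correlation stayed past its threshold (camera adjusted p = 1.14e-05). A weak trend remained after the removal. Over protein-coding genes with a mean log2 level above 5, Spearman's rho of log2 change and span was 0.055, against 0.355 before. The trend may still account for part of the change. With an estimated correlation the list was not past the threshold even before the removal (adjusted p = 0.298), and the labelled genotype stays open as an untested explanation.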
